A study of Mus musculus with 2 samples.

How the data were processed

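Chromatin immunoprecipitation with an antibody to NRF1, followed by sequencing, was carried out on 2 libraries of MEL cells, replicates 1 and 2 of 1 group per the labels. The sources used here were peak lists and the text descriptions that accompany them. Per the READMEs, reads were aligned to mm10, alignments were filtered, regions were called against a control alignment, and the thresholded lists had a further list of regions among their sources. The aligner and the peak caller are not given in the sources used here. The number of reads per library is unknown, so no interval that needs the depth is given, and the exact intervals below cover the counting of peaks, sites or genes only.

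Per the READMEs, the lists came from 2 processing rounds. The first gave an unfiltered list for each library (168591 and 300000 regions) and for both pooled (300000 regions), and from these an optimal list (11140 peaks) and a conservative list (10291 peaks) over both libraries. The second gave lists ranked by the irreproducible discovery rate (IDR), a pooled thresholded list (11191 peaks), a conservative list (10305 peaks) and a thresholded list for each library (4917 peaks for replicate 1, 9187 for replicate 2). The optimal list was the main peak set, fixed before the data were examined. Peaks were thus called by the authors both per library and on the pooled libraries, and the overlap of replicates was taken from the lists of the single libraries.

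The deposited signal value of each peak was made by the authors relative to control in a way not given in the sources used here; it describes and ranks peaks within 1 list and is not compared between lists made separately. Each of the 11140 optimal peaks has its region, summit and signal value, within 1 part in 100000, in the pooled unfiltered list, so signal values from these lists are on 1 scale. The deposited score of each thresholded or ranked region runs to 1000, and on the 4 ranked lists it equalled -125 times log2 of the IDR, capped at 1000, within 1 unit in 100% of regions. The deposited −log10 of the IDR in the ranked lists gave the regions past the authors' threshold of 0.05 and a stricter one of 0.01, a score of 830 or more. The deposited position of each summit is an offset in bp from the start of the peak. Some regions of the optimal list are repeated with a further summit, so its 11140 peaks cover 11115 distinct regions.

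The reference was GRCm38, the assembly that mm10 names, with the GENCODE M21 annotation, and every peak lay within the chromosome lengths of that assembly. The 21938 protein-coding genes of the nuclear chromosomes had 93513 annotated TSSs. A gene was called bound when a summit lay within 1 kb of any of its TSSs. A promoter was CpG-rich when the 500 bp to either side of the TSS had an observed over expected CpG ratio of at least 0.6 and a GC content of at least 0.55. Offsets are given along the strand of the gene, negative upstream. Coordinates are counted from 1.

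Shares carry exact Clopper-Pearson 95% intervals. Peaks were set against the regions of the unfiltered lists that overlap no peak, 288435 of them for the optimal list, and against 100 seeded shuffles within chromosomes. Words were counted in windows of 50 bp to either side of the summit and in windows of the same width centred 250 bp left and right of it. Fisher's exact test, two-sided, was used throughout, with Benjamini-Hochberg adjustment over the 10 words, the 30699 eight-mers found in at least 20 windows, and the 22 gene lists. p-values below 1e-300 were written as 1e-300, and eight-mers tied there were ordered by the logarithm of the upper-tail p. Correlations and the trend over signal rank had permutation tests with 100000 resamples, whose smallest p is 1e-05. The gene lists were fixed before the data were examined.

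Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The functions behind the main tests were tested on simulated data. The overlap function differed from bedtools 2.31.1 in 0 of 4000 simulated intervals. With nothing planted 0 of 32895 eight-mers were called, and 2 of 2 planted eight-mers came first when a site was planted. Both checks used flank windows with shuffled bases, so they do not cover differences in base composition between summits and flanks. With genes bound at random, any list was called in 2 of 50 draws, and a list with raised binding was called in 50 of 50. With genes bound by CpG decile alone, the Mantel-Haenszel test called any list in 0 of 50 draws and Fisher's exact test in 50 of 50; a list with its odds raised 4 times was called by the former in 49 of 50, at a median odds ratio of 3.96. The permutation test gave a p under 0.05 in 5 of 100 draws without a trend, in 6 of 100 without a correlation and in 100 of 100 with a planted correlation.

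The genes named were chosen by a rule fixed before the data were examined: the nearest genes of the 10 strongest peaks, in each gene list the 3 bound members with the highest signal and the first 2 unbound members in alphabetical order, a set of genes of prior interest whether bound or not, and the 5 eight-mers with the smallest p. Further bound members were named after their values were seen where a list had 8 or fewer of them, along with Twnk. The globin gene Hbb-b1, one of the genes of prior interest, has no entry under that name in the annotation and was not analysed here.

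Alternatives fixed before the data were examined were the conservative list, the list of each library alone, the 2000 strongest peaks, the stricter IDR, other overlaps, TSS windows of 500 bp and 5 kb, 1 TSS per gene, other forms of the site, a window of 100 bp, deciles of promoter CpG count with a Mantel-Haenszel test, only genes with the site near a TSS, and each peak given to its nearest gene only. The pooled list of the second processing round and the palindrome with at most 3 mismatches were added after the data were seen. The 18 mitochondrial and 3 scaffold peaks were left out of the comparisons. Signal tracks and alignments were not used here.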

Results

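The binding of nuclear respiratory factor 1 (NRF1), a transcription factor that recognises the palindrome TGCGCATGCGCA, was mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in MEL cells, a mouse erythroleukaemia line that grows as immature red cell precursors. The 2 libraries formed 1 group, so the design implied no contrast between conditions, and the questions were where NRF1 bound, with which sequence, at which genes and how well the libraries matched. Both libraries carried the same biosample record, so every p-value below measures only the spread between peaks or genes in these samples, which may be technical. The data were lists of peaks in mm10 (GRCm38) coordinates, and the number of reads behind them was unknown. Each peak's signal value is the authors' own and was used only to describe and rank peaks within a list.

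The list kept from both libraries together, named optimal in the labels, held 11140 regions with a median width of 316 bp. The strongest peak lay at the promoter of Rock1, a kinase that controls the actin cytoskeleton, at positions 10182058 to 10182434 of chromosome 18, with a signal of 628 against a median of 45.8 over the list. Its summit lay at offset -200 bp from the transcription start site (TSS) of Rock1 and held TGCGCATGCGCG at positions 10182218 to 10182229. The next strongest peaks lay at Prelid3b, which encodes a PRELI domain protein (chromosome 2, 174472831 to 174473358), at Rab3gap2, a subunit of the Rab3 GTPase-activating complex (chromosome 1, 185203868 to 185204244), and at Ift172, a subunit of the intraflagellar transport machinery (chromosome 5, 31290997 to 31291364). Ccdc93 of the endosomal sorting machinery, Trappc1 of vesicle tethering, Lig4 of DNA end joining, Pop7 of ribonuclease P, the ubiquitin ligase gene Trim23 and the stress kinase gene Map2k7 completed the 10 strongest, the last with a signal of 611. Each of these 10 summits lay within 1 kb of a TSS, and 8 of them held the word GCGCNNGCGC within 50 bp. Of the 11140 regions, 11119 lay on the nuclear chromosomes, 18 on the mitochondrial genome and 3 on scaffolds, and the nuclear ones entered every comparison below. The thresholded list of replicate 1 alone held 4917 peaks and that of replicate 2 alone 9187. The peaks of Rab3gap2, Ift172, Trappc1, Lig4 and Trim23 were missing from replicate 1's own list although they were among the strongest of the list from both libraries.

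Nearly every NRF1 peak of replicate 1 was also a peak of replicate 2, while replicate 2 held many weaker ones besides. Of the 4917 peaks of replicate 1, 4840 (98.4%, 95% interval 98.0% to 98.8%) overlapped a peak of replicate 2 by at least 1 bp, against 2.26% of the lower-ranked regions of replicate 1. Of the 9187 peaks of replicate 2, 53.9% (52.8% to 54.9%) overlapped a peak of replicate 1, against 0.0241% of its lower-ranked regions. Promoters bound in both libraries included those of the mitochondrial RNA polymerase gene Polrmt, the cytochrome c gene Cycs and Nrf1 itself. The promoters of the mitochondrial methyltransferase gene Tfb1m and of Tal1, an erythroid transcription factor, carried a peak in replicate 2 alone, with signals of 38.7 and 41.7 in the optimal list. Both overlaps had a p at or below 1e-300, the smallest value written, by Fisher's exact test, two-sided. The second is not a separate test. Nearly all replicate 1 peaks overlapped replicate 2 peaks, which left few for the lower-ranked regions of replicate 2 to meet. Across 10605 optimal peaks with a region in both libraries, the log10 signals correlated with Spearman's rho 0.904 and Pearson's r 0.927, each with a permutation p of 1e-05, the smallest the permutations can give; these are correlations across peaks, which are not independent replicates. Among the 2000 strongest peaks rho was 0.683 and r was 0.628.

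NRF1 peaks lay mainly at promoters of protein-coding genes. Of the 11119 nuclear peaks, 7795 (70.1%, 95% interval 69.2% to 71.0%) had their summit within 1 kb of a TSS, against 9.05% of the lower-ranked regions and a mean of 4.196% over 100 shuffles within chromosomes. The summits near a TSS clustered just upstream of it, with a median offset of -25 bp and quartiles of -94 and 14 bp. A further 1270 peaks (11.4%) lay in introns and 219 (1.97%) in exons of protein-coding genes, and 1835 (16.5%) lay outside protein-coding genes. Promoter peaks had a median signal of 62.0, compared with 24.5 for intronic peaks and 28.3 for peaks outside protein-coding genes. The excess over the lower-ranked regions had an odds ratio of 23.6 (Fisher's exact test, two-sided, p at or below 1e-300). With a window of 5 kb the share near a TSS was 79.3%, but the share of lower-ranked regions was 26.5% and the odds ratio fell to 10.6.

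The NRF1 site lay directly under the summits. The word GCGCNNGCGC, the core of the palindrome with any central pair, occurred within 50 bp of 2219 of 11119 summits (19.96%, 95% interval 19.2% to 20.7%), against 221 of 22238 windows of the same width centred 250 bp to either side (0.994%). Uqcrc1, which encodes a core subunit of respiratory complex III, and Psma2, a proteasome subunit gene, carried the whole palindrome TGCGCATGCGCA at the summit, with signals of 562 and 472. Of 3782 occurrences within 250 bp of a summit, overlapping ones included, 2127 (56.2%) were centred within 20 bp of it. Promoter peaks held the word more often (24.2%) than peaks over 1 kb from a TSS (9.90%), with an odds ratio of 2.91 and a p of 2.75e-74. The enrichment over the flanks had an odds ratio of 24.8 (Fisher's exact test, two-sided, p at or below 1e-300). The share depended on the list and the word: it was 38.4% with replicate 1's list alone, 57.8% among the 2000 strongest peaks, 3.15% for GCGCATGCGC alone, and 43.6% for the palindrome with at most 3 mismatches, against 3.44% in the flanks.

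**Figure D1:**
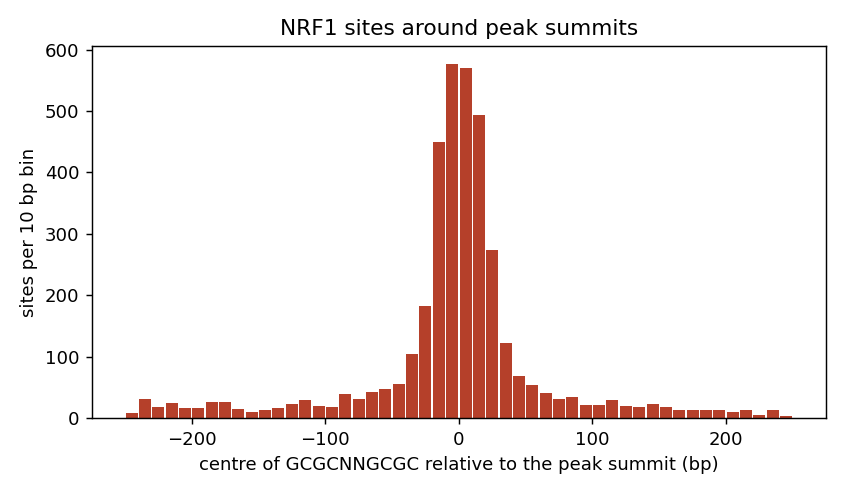
Number of GCGCNNGCGC sites in 10 bp bins (vertical axis) by the distance of the site's centre from the peak summit in bp (horizontal axis), over the optimal nuclear peaks. The sites gather at the summit, with 2127 of 3782 centred within 20 bp of it.

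The words of other factors were also more frequent at NRF1 summits than beside them, to a lesser degree. The NRF1 word was 20.1 times as frequent at summits as in the flanks. The CTCF word, bound by the chromatin loop anchor CTCF, followed at 7.48 times (1.04% of summits), then the CREB/ATF word at 4.94 times (1.18%), the ETS word at 3.90 times (2.44%) and the NFY word at 3.12 times (4.60%). SP/KLF, E-box and YY1 words reached ratios of 2.49, 1.91 and 1.77. The antioxidant response element, the site of NFE2L1, which shares the short name NRF1, reached 1.33 times (5.41% of summits against 4.08% of flanks), and the GATA word of erythroid GATA1 reached 1.23 times (6.32% against 5.15%). Each of the 10 words was called by Fisher's exact test with Benjamini-Hochberg adjustment over the words, the largest adjusted p being 0.00143 for YY1. The test treated the summit and flank windows of a peak as separate and did not allow for differences in base composition between them. An excess of a word therefore does not by itself show that its factor binds there. Among 30699 eight-mers tested, each counted with its reverse complement, 2256 were more frequent at summits and 3603 less frequent at an adjusted p under 0.05. The 5 with the smallest p were GCATGCGC (10.3% of summits against 0.279% of flanks), CATGCGCA (8.63% against 0.162%), GCCTGCGC (12.0% against 1.08%), CGCAGGCG (10.2% against 0.805%) and GCGCACGC (9.10% against 0.684%). With replicate 1's list alone 1420 eight-mers were more frequent at summits, and 756 among the 2000 strongest peaks.

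The strongest NRF1 peaks carried the site most often. From the lowest to the highest quintile of the peaks by signal, the share with GCGCNNGCGC within 50 bp of the summit was 1.53%, 4.36%, 10.03%, 26.98% and 56.9%. The flanking windows held the word in 0.585% of cases in the lowest quintile and 1.55% in the highest. The share of summits within 1 kb of a TSS went from 54.3% to 87.7% over the same quintiles. Peaks found in both libraries held the word in 38.7% of cases, peaks found in replicate 2 alone in 8.16%, and the 2880 peaks found in neither library's own list in 2.01%. The trend of the word over signal rank had a permutation p of 1e-05, the smallest the permutations can give (two-sided). Without replicate 2, the share in the lowest quintile was 14.8% of a list with fewer weak peaks, and within the 2000 strongest peaks the shares of the lowest and highest quintile were 52.5% and 62.0% (permutation p of 0.00097).

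**Figure D2:**
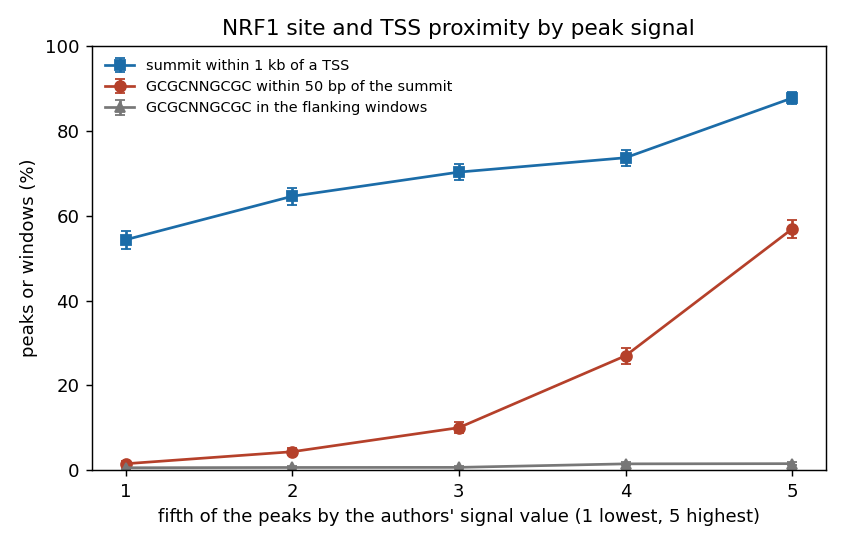
Share of peaks or windows in percent (vertical axis) in 5 equal groups of the optimal nuclear peaks ordered by the authors' signal value (horizontal axis), for summits within 1 kb of a TSS (squares), GCGCNNGCGC within 50 bp of the summit (circles) and the same word in the flanking windows (triangles), with exact 95% intervals. The word rose from 1.53% to 56.9% of summits and stayed at or below 1.55% of the flanks.

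Most copies of the NRF1 site away from promoters carried no peak. Of 1655 copies of GCGCATGCGC on the chromosomes, 390 (23.6%, 95% interval 21.5% to 25.7%) lay in a peak. Within 1 kb of a TSS 331 of 453 copies (73.1%) did so, against 59 of 1202 (4.91%) farther away. In CpG-rich surroundings 69.6% of copies were occupied, against 3.96% in CpG-poor ones, and among copies over 1 kb from a TSS the shares were 21.7% of 120 and 3.05% of 1082. The central pair of the word went with occupancy at promoters: GCGCAGGCGC was in a peak in 76.0% of 1115 cases, GCGCACGCGC in 72.4% of 888 and GCGCAAGCGC in 66.4%, but GCGCGCGCGC in 30.1% of 1762, GCGCCCGCGC in 21.9% of 657 and GCGCCAGCGC in 18.3% of 229. The intervals were 73.3% to 78.4% for the pair AG and 28.0% to 32.3% for GC. Copies were counted at every start position, so a run of GC repeats gives several overlapping copies of GCGCGCGCGC. Its share and interval therefore do not rest on separate sites. Fisher's exact test, two-sided, gave a p of 2.38e-177 for distance, 2.21e-178 for CpG content and 1.85e-12 for CpG content away from promoters. With the word GCGCNNGCGC, which has 27519 copies, 12.7% were occupied, and the difference by CpG content away from promoters narrowed to 5.61% against 1.89%.

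**Figure D3:**
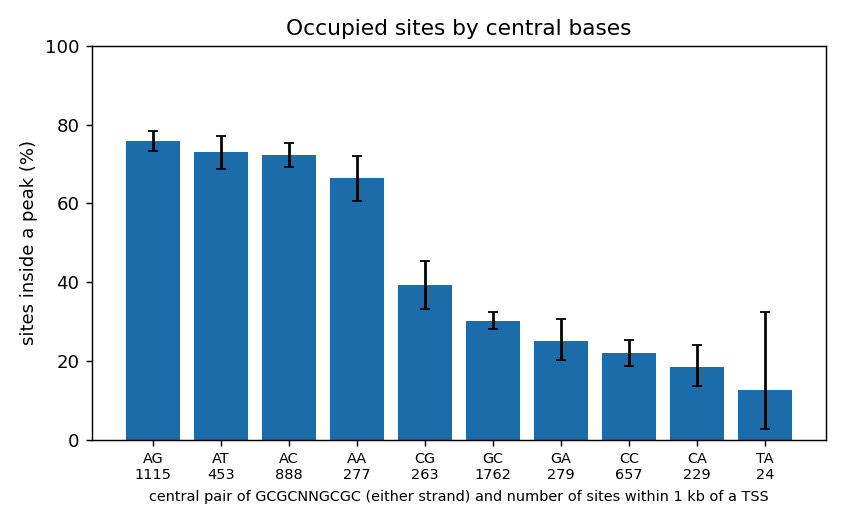
Share of GCGCNNGCGC sites within 1 kb of a TSS that lie in an optimal peak, in percent (vertical axis), by the central pair of bases read on either strand, with the number of sites under each pair (horizontal axis) and exact 95% intervals. Sites with AG, AT, AC or AA in the centre lie between 66.4% and 76.0%, the others at or below 39.2%. Overlapping copies within GC repeats were each counted.

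NRF1 peaks lay at the promoters of many protein-coding genes, and several of its textbook targets were among them. A peak summit lay within 1 kb of a TSS of 7214 of 21938 genes (32.9%, 95% interval 32.3% to 33.5%). Polrmt, the mitochondrial RNA polymerase, had a signal of 530.4 (chromosome 10, 79746409 to 79746830), Cycs, cytochrome c, 300.2 (chromosome 6, 50566499 to 50566765), Tfb2m, a mitochondrial transcription factor, 198 (chromosome 1, 179546167 to 179546383), and the mitochondrial chaperonin gene Hspd1 291 (chromosome 1, 55088152 to 55088428). The Nrf1 promoter itself carried a peak with a signal of 311 (chromosome 6, 30047934 to 30048265). Peaks also lay at Gabpa, an ETS factor of the same nuclear respiratory class (259), at Fmr1, the fragile X gene (348), at the initiation factor gene Eif2s1 (316) and at the transcription factor gene Yy1 (208). Nfe2l1 carried a weak peak at offset -467 bp, with a signal of 58.1. Tfam, the packaging factor of mitochondrial DNA, had GCGCNNGCGC within 1 kb of a TSS but no peak; its region in the pooled unfiltered list, which holds each of the 11140 optimal peaks with its signal, had a signal of 7.10 against a median of 45.8 over the peaks. Cox4i1, Ndufs1, the coactivator gene Ppargc1a, Nfe2l2 and the germline genes Dazl, Asz1 and Taf7l had no peak either, although each of the last 3 had the word near a TSS. Of 55 named genes without a peak, 41 had a region in that unfiltered list, with a median signal of 8.26.

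Genes with divergent promoters, with TSSs of a pair of genes head to head within 1 kb, had a peak more often than others. A peak near such a pair can count for both genes, and each gene of the pair entered the tests. This by itself raises the share of divergent genes, and no version of this comparison gave each peak to 1 gene. The values below therefore do not show that NRF1 prefers divergent promoters. A peak lay at 68.8% of 2410 genes with such a promoter and at 28.4% of 19528 other genes, with an odds ratio of 5.56. Sdhd, a subunit gene of succinate dehydrogenase, and Timm8b, of mitochondrial protein import, shared 1 such peak, with a signal of 536 (chromosome 9, 50603770 to 50604079). CpG-rich promoters were bound in 57.8% of 8406 cases and others in 17.4% of 13532, and among CpG-rich promoters the share was 75.5% for divergent and 53.7% for other genes (Fisher's exact test, two-sided, p of 2.85e-59). The first 2 differences had a p at or below 1e-300. The share of all genes bound was 18.99% with replicate 1's list alone and 9.36% with the 2000 strongest peaks.

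Genes of the mitochondrial respiratory chain and of mitochondrial protein synthesis were bound at more than their share. Of the complex I genes 35 of 45 (77.8%) had a peak, led by Ndufa8 (560), Ndufb10 (548) and Ndufa6 (545), while Ndufa1 and Ndufa7 had none. Of the nuclear-encoded genes of complexes II to V 41 of 58 (70.7%) were bound, led by Uqcrc1 (562), the ATP synthase gene Atp5c1 (549.7) and the succinate dehydrogenase gene Sdha (545), without Atp5a1 and Atp5b. The mitochondrial ribosome had 59 of 82 genes bound (72.0%), led by Mrpl36 (539.6), Mrpl54 (527) and Mrps24 (523), without Mrpl15 and Mrpl16. The numbers in brackets are signal values in the optimal list. The adjusted p was 3.15e-09, 1.65e-08 and 7.99e-12 in turn, by Fisher's exact test against all other protein-coding genes with Benjamini-Hochberg adjustment over the 22 lists. All 3 calls were kept within deciles of promoter CpG count, where the odds ratios fell from 7.17, 4.94 and 5.27 to 3.60, 2.83 and 3.06, with adjusted p of 0.000552, 0.000962 and 0.000111 by a Mantel-Haenszel test.

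Genes of mitochondrial DNA maintenance, protein import and the tricarboxylic acid cycle were also bound more often than other genes, but these calls ended once promoter CpG content was held level. Of the genes that copy, package and transcribe mitochondrial DNA 15 of 21 (71.4%) had a peak, led by Polrmt, the termination factor family gene Mterf3 (254) and Tfb2m; the helicase gene Twnk had a signal of 26.1 and Tfb1m 38.7. Protein import had 24 of 37 genes bound (64.9%), led by Chchd4 of the intermembrane space (568), the chaperone gene Hspa9 (557) and Timm8b, without Dnajc19 and Gfer. The tricarboxylic acid cycle had 14 of 18 bound (77.8%), led by Dld (512), Ogdh (485) and Idh3a (439.9), all dehydrogenase subunits, without Dlst and Idh2. The adjusted p was 0.000696, 0.000109 and 0.000168 by Fisher's exact test. Within deciles of promoter CpG count the odds ratios fell from 5.11, 3.78 and 7.16 to 2.68, 1.66 and 2.75, with adjusted p of 0.0804, 0.173 and 0.128, which ended these calls. The 2.68 and 2.75 lay above the 2.14 of the 74 genes of DNA replication and the cell cycle, whose call was kept. With lists of 21 and 18 genes, the lost calls therefore do not show that CpG content accounts for their binding. Among genes with GCGCNNGCGC near a TSS 4 of 5 (odds ratio 1.96), 10 of 13 (1.63) and 3 of 3 were bound, with no call among so few genes. Among the 2000 strongest peaks only 1 of the 21 genes of mitochondrial DNA maintenance was bound (4.76%, against 9.36% of other genes).

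Genes of nuclear transcription and of translation were bound more often than other genes as well. RNA polymerase subunits reached 25 of 28 (89.3%), led by Polr2j (578), Polr2e (534) and Polr2f (508), without Polr1e and Polr2m. Translation initiation factors reached 35 of 40 (87.5%), led by Eif1 (590.0), Eif3h (545) and Eif3k (532), and tRNA synthetases of the cytosol and mitochondria 30 of 37 (81.1%), led by Kars (571) and the mitochondrial enzymes Vars2 (558) and Yars2 (497). Cytosolic ribosomal proteins reached 51 of 85 (60%), led by Rpl19 (604), Rpl10 (509) and Uba52 (490.3). The adjusted p was 3.15e-09, 8.34e-12, 6.10e-09 and 6.58e-07 by Fisher's exact test. RNA polymerase subunits fell to 20 of 28 (71.4%) with the conservative list and 11 of 28 without replicate 2, and were called higher with each. Polr2j and Polr2e had no peak in replicate 1's own list despite signals of 289 and 286 in that library. Within deciles of promoter CpG count the odds ratios of the first 3 lists fell from 17.1, 14.4 and 8.78 to 8.66, 6.17 and 6.001, with their calls kept. The call for cytosolic ribosomal proteins ended within deciles of promoter CpG count, where the odds ratio was 1.45 instead of 3.08 (adjusted p of 0.128). Among genes with GCGCNNGCGC near a TSS 7 of 7 RNA polymerase genes and 17 of 20 cytosolic ribosomal protein genes were bound, the latter with an odds ratio of 2.78, and with so few genes neither list was called (adjusted p of 0.163 each).

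Genes of DNA replication, DNA repair, protein turnover and cilia were bound more often than other genes too. DNA repair had 45 of 60 genes bound (75%), led by Lig4 (614), the nucleotide excision gene Xpa (551) and the BRCA2 partner gene Palb2 (547). DNA replication and the cell cycle had 50 of 74 (67.6%), led by Pola2 of DNA polymerase alpha (573), the licensing factor gene Cdt1 (533) and the cyclin gene Ccna2 (507), without Aurkb and Ccnd1. Autophagy had 25 of 33 (75.8%), led by Atg10 (558), Wipi2 (544) and Wdr45 (519.7), and the proteasome 33 of 47 (70.2%), led by Psmc4 (525), Psmd14 (512) and Psma2 (472). Intraflagellar transport and the basal body had 31 of 51 (60.8%), led by Ift172 (617), Ift80 (594) and Ift122 (583). The adjusted p was 1.51e-10, 3.60e-09, 1.01e-06, 4.08e-07 and 0.000101 in turn by Fisher's exact test. Within deciles of promoter CpG count the odds ratios of the first 4 lists fell from 6.16, 4.27, 6.40 and 4.83 to 3.22, 2.14, 3.60 and 3.20, with their calls kept. The call for intraflagellar transport ended within deciles of promoter CpG count, where the odds ratio was 1.84 instead of 3.17 (adjusted p of 0.0829), and that for the proteasome among the 2000 strongest peaks (0.467). Among genes with GCGCNNGCGC near a TSS the smaller lists of the proteasome (11 of 12 bound, adjusted p of 0.174) and intraflagellar transport (15 of 16, 0.0533) were not called although their odds ratios of 5.39 and 7.36 lay above the 4.83 and 3.17 over all genes, while that of autophagy fell from 6.40 to 1.47 (9 of 12, 0.838).

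Neither list of red cell genes was called in the main test, although heme synthesis genes had a higher bound share than other genes (57.1% against 32.9%). Of 32 erythroid regulators and products 7 had a peak (21.9%, 95% interval 9.28% to 39.97%). Among them were Tfrc, the transferrin receptor that brings iron into the cell (415; chromosome 16, 32608697 to 32608991), the membrane skeleton gene Epb41 (278), and the regulators Lmo2 (55.3), Tal1 (41.7) and Ldb1 (26.0). The erythroid master regulator genes Gata1 and Klf1 and the globin gene Hba-a1 had no peak. Of 14 heme synthesis genes 8 were bound (57.1%, 28.9% to 82.3%): the housekeeping first enzyme gene Alas1 (521; chromosome 9, 106247747 to 106248123), the mitochondrial transporter gene Abcb10 (471), Uros (467), Tmem14c (183), Cpox (107), Hmbs (88.6), Fech (48.5) and Ppox (24.5). The erythroid isoform gene Alas2 had no peak. Neither list passed the test, with an adjusted p of 0.258 and 0.0868 by Fisher's exact test. The heme list passed with replicate 2's list alone (adjusted p of 0.00733), with replicate 1's list alone (0.0402), with the list of the second processing round (0.0220) and with a window of 500 bp (0.0493).

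Genes of other tissues were bound less often than other genes. None of 1135 olfactory receptor genes had a peak (0%, upper limit 0.324%). Liver markers had 1 of 33 bound, Apoh, which encodes a plasma apolipoprotein, with its summit at offset 615 bp (486). Neuronal markers had 4 of 37 (10.8%): the synaptic vesicle genes Syn1 (423) and Syp (332), the glutamate receptor gene Gria3 (31.3) and the neuronal enolase gene Eno2 (16.5). Germline and meiosis genes had 5 of 50 (10%): the tudor domain genes Tdrd9 (491) and Tdrd5 (358), Piwil4 of the piRNA pathway (338), Tex19.2 (258) and the synaptonemal complex gene Syce2 (39.8). Hox genes had 6 of 39 (15.4%), all weak, from Hoxc9 (59.2) and Hoxb13 (35.4) down to Hoxa7 (13.8), and Hoxc5 and Hoxc10 shared 1 peak; without replicate 2 none of the 39 and 2 of the 37 neuronal markers were bound. The adjusted p was 2.24e-202, 8.32e-05, 0.00313, 0.000308 and 0.0275 in turn by Fisher's exact test. The liver call ended within deciles of promoter CpG count, where the odds ratio was 0.128 instead of 0.0637 (adjusted p of 0.207), and turned among genes with GCGCNNGCGC near a TSS, where Apoh was the 1 gene left. The neuronal call ended with the conservative list (0.0556), and among the 2000 strongest peaks the olfactory list alone of these 5 kept its call; there 9.37% of other genes were bound, and the odds ratio was 0.269 for neuronal markers (0.247 over all peaks), 0.403 for germline genes (0.226) and 0 for Hox genes (0.371).

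Over the 22 lists, 15 were bound more often than other genes, 5 less often, and 2 were not called. Respiratory chain, mitochondrial ribosome, RNA polymerase, initiation factor, tRNA synthetase, replication, repair, proteasome and autophagy genes were the 10 lists still called higher within deciles of promoter CpG count, with complexes II to V counted apart from complex I. The list of either library alone gave 16 lists higher and 5 lower. Without replicate 2, where 18.99% of genes were bound, the share fell over 1.5 times to 38.1% for mitochondrial DNA maintenance, 44.4% for the tricarboxylic acid cycle, 43.9% for the mitochondrial ribosome, 39.3% for RNA polymerase, 51.4% for tRNA synthetases, 42.6% for the proteasome, 41.9% for replication and 33.3% for intraflagellar transport, all still called higher. Among genes with GCGCNNGCGC near a TSS, 7 lists were higher and 4 lower.

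**Figure D4:**
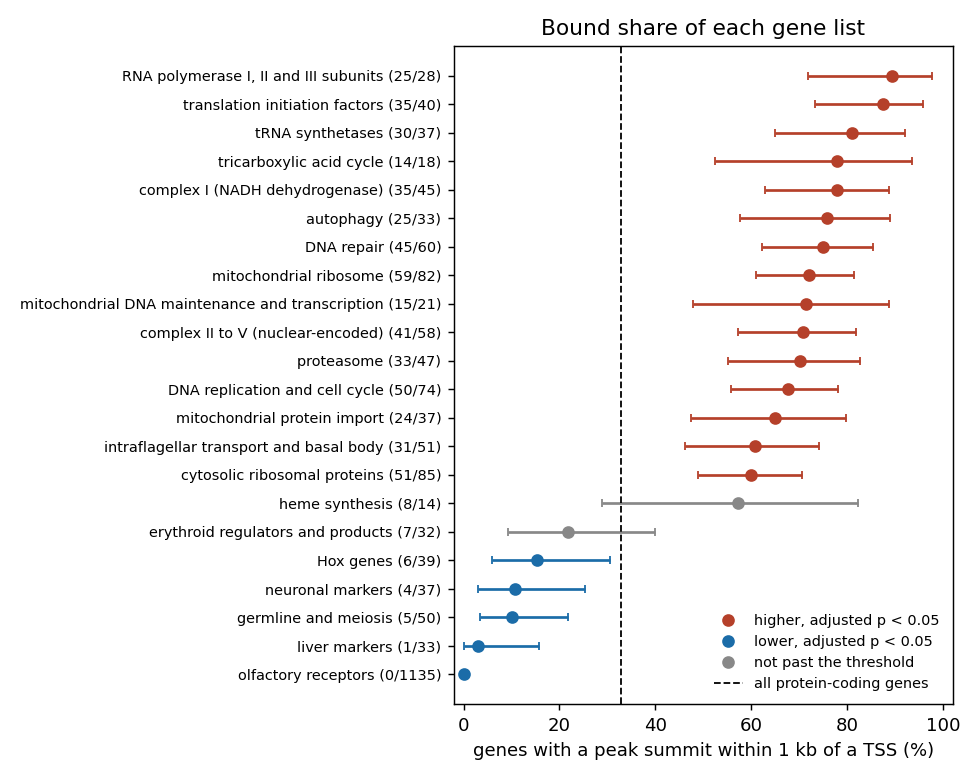
Share of the genes of each list with a peak summit within 1 kb of a TSS, in percent (horizontal axis), for the 22 lists with bound and total genes in brackets (vertical axis), with exact 95% intervals and the share of all protein-coding genes as a dashed line at 32.9%. Points are coloured by whether the list was higher or lower than other genes at an adjusted p under 0.05, and RNA polymerase subunits stand highest in this list at 89.3%.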

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

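The tests of degenerate sites and of other factors' words were chosen, or given their present wording, after the results were seen. The same holds for the tests of the steps before and after the ranking of the mitochondrial regions. The other tests of explanations below had been set beforehand.

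The optimal list held 18 peaks on the mitochondrial genome, which the comparisons did not use. Counts above 3 were taken up here, a limit set for reporting and not a statistical bound. They covered 32.4% of its 16299 bp, with a median signal of 45.7, and the best of them ranked 4014. The word GCGCNNGCGC is argued against as the cause, since the mitochondrial genome holds 0 copies of it. In the test set beforehand, 0 of the 18 summits carried the palindrome with at most 2 mismatches. That count alone decides little, since only 8.14% of nuclear summits in the middle quintile by signal (30.9 to 78.4) carried it. Sites with more mismatches were not tested here. The lists thresholded in the second processing round held none of these peaks, and a loss before the ranking is argued against because 19 mitochondrial regions stood in the ranked pooled list; the bound had been set for any step that differed between the rounds and was narrowed to steps before the ranking once the ranked lists had been seen. What stays open is a filter after the ranking, whose nature is not given in the sources used here. In the 4 overlapping ranked lists 16, 12, 14 and 11 mitochondrial entries stood past the IDR threshold, so the threshold itself had not removed them. Summed over these lists, all 53 such entries were missing from the thresholded ones, against 0.0477% of the nuclear entries past the threshold. The lists thresholded in the second round also held 0 scaffold regions, against 3 in the optimal list. Such a filter may explain why the rounds differ but not why the regions were called.

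Weak NRF1 peaks rarely held the site, with GCGCNNGCGC at 1.53% of summits in the lowest quintile and 56.9% in the highest. Summits placed away from the site are argued against, since only 3.87% of the lowest quintile held the word within 250 bp. Degenerate sites with at most 3 mismatches to the palindrome are argued against for most of these peaks. Such sites lay at 8.09% of summits in the lowest quintile, compared with 92.9% in the highest. Flanks over all peaks held them in 3.44% of cases, so some weak peaks may have such sites. Sites with more mismatches, or with only a part of the palindrome, were not tested. Open chromatin or sites of other factors drawn into the list stay open as a candidate explanation, with mixed evidence: at lowest-quintile summits the GATA word (9.76% against 6.32% of flanks), the CTCF word (1.89% against 0.315%) and the NFY word (3.51% against 1.62%) were in excess, with a largest adjusted p of 2.56e-06. From weak to strong, only the GATA word passed from excess (1.54 times the flanks in the lowest quintile) to a deficit (0.398 times in the highest); the NFY word was in excess in every quintile, most in quintiles 2 and 3 (4.73 and 4.83 times, against 2.17 in the lowest and 2.34 in the highest), and the CTCF word was 6, 17, 11, 3 and 6 times as frequent as in the flanks from the lowest to the highest quintile, with 9 summit windows in each of the last 2.

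Chromosome 11 held 14.2% of the peaks of the lowest quintile and 10.2% of those of the highest (odds ratio 1.46, Fisher's exact test p of 5.25e-05). This comparison was not among the planned ones, and its p is not adjusted for the choice of this chromosome among the autosomes. Chromosome 19 leaned nearly as far to weak peaks, with 203 in the lowest 2 quintiles and 78 in the highest, against 602 and 226 on chromosome 11. More CpG-rich promoters on chromosome 11 are argued against as the whole cause, since 28.6% of its 706 CpG-rich promoters carried a peak of the lowest 2 quintiles, against 19.1% of 7527 on other autosomes, a ratio of 1.499 with a p of 6.74e-09. Extra copies of the chromosome in these cells could account for it and stay open: in both libraries, unselected regions over 10 kb from a TSS were denser for their GC content on chromosome 11 than on 17 of 18 other autosomes, chromosome 15 being the exception. Chromosome 15 stood farther over the density set by GC content, by 19.9 and 37.3 regions per Mb in replicates 1 and 2. The values for chromosome 11 were 14.5 and 23.3. Chromosome 15 nevertheless held fewer peaks of the lowest 2 quintiles than chromosome 11. It leaned to weak peaks too, but less than chromosomes 11 and 19. Density therefore does not by itself account for the number of weak peaks on chromosome 11. No copy number was measured here.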

How the results depend on the processing

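The pooled list of the second processing round and the palindrome with at most 3 mismatches were chosen after the data were seen. Of the values that answer a comparison, 49 stayed on their side of the threshold, or within their interval or 1.5 times the count, under their alternatives and 12 moved; none reversed. The lists of single libraries gave 4917 to 9187 peaks, 1420 to 1931 eight-mers more frequent at summits and 18.99% to 28.9% of genes bound, with fewer peaks in each list. The 2000 strongest peaks gave 756 such eight-mers, 18.5% of GCGCATGCGC copies in a peak and 9.36% of genes bound, again with fewer peaks. The word GCGCNNGCGC gave 12.7% of 27519 copies in a peak: GCGCGCGCGC makes up 16678 of them, 5.05% in a peak, and the others reached 24.5%. Overlapping copies within GC repeats were each counted, so the 16678 are not all separate sites. Genes bound came to 32.0% with the conservative list, 31.5% within 500 bp and 36.3% within 5 kb. Among genes with GCGCNNGCGC near a TSS 11 lists were called, with fewer genes in each. A pair of gene lists reversed, neither past the threshold: mitochondrial DNA maintenance stood at 4.76% among the 2000 strongest peaks, against 9.36% of other genes, and liver markers at 100% among genes with the word, where 1 gene remained; the cause was not tested. Of the other values, on single lists and named genes, 1064 stayed the same, 56 moved, 20 fell below the threshold and 4 rose past it. Of 80 named bound genes, 19 lost their peak without replicate 2, 19 among the 2000 strongest, 9 with each peak given to its nearest gene only and 1 within 500 bp. Replicate 1's list lacked 44 of its own 100 strongest regions, so a loss without replicate 2 need not mean a weak signal. Genes without a peak in that list included Rpl19, Uqcrc1 and Alas1, with signals of 299.6, 300 and 297 in replicate 1, and Tfb1m, with 6.94. No paired analysis was possible because the design has 1 group. The depth of the libraries is unknown, so a missing peak shows no absence of binding.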

Other observations

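The symbol families, the peaks away from promoters, the strongest regions of each library and the site-by-CpG classes below were examined only after the peak lists had been seen.

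Gene families outside the fixed lists were compared by shared symbol stem, for the 129 families with at least 15 members. RNA-binding motif genes (Rbm) had 29 of 39 members bound (74.4%, adjusted p of 2.47e-06 by Fisher's exact test) and the DEAD-box helicase genes (Ddx) 27 of 36 (75%, adjusted p of 4.40e-06). Ubiquitin-conjugating and related genes (Ube) followed with 29 of 42, the Integrator complex (Ints) with 13 of 15, TBP-associated factors (Taf) with 17 of 22, Mediator (Med) with 21 of 30, nucleoporins (Nup) with 16 of 21 and small GTPases of vesicle traffic (Rab) with 39 of 69. In all 39 families were bound more often than other genes, 43 less often and 47 were not called. Within deciles of promoter CpG count only Rbm (adjusted p of 0.00552) and Ddx (0.0486) were still called higher, with odds ratios of 3.92 and 3.51; those of the smaller families Ints (8.26), Nup (4.08) and Taf (4.01) were larger, but were not called with so few members.

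Among families bound less often, none of 67 histone genes of the Hist clusters had a peak, and the difference held within deciles of promoter CpG count (adjusted p of 9.16e-16 by a Mantel-Haenszel test). The signalling genes Wnt (0 of 19, adjusted p of 0.00180), the developmental regulators Sox (1 of 19, 0.00180), the collagens Col (2 of 45, 0.00210), the synaptotagmins Syt (0 of 15, 0.0102), the cytochromes P450 Cyp (2 of 96, 0.0172), the orphan receptors Gpr (9 of 73, 0.0337), the keratins Krt (0 of 53, 0.0340) and the cadherins Cdh (1 of 23, 0.0421) were likewise still lower within those deciles, which made 9 families. The vomeronasal receptors Vmn had 1 of 331 bound and an odds ratio of 0.0508 within the deciles (adjusted p of 0.0726).

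The site and the CpG content of a promoter each went with binding. CpG-rich promoters with GCGCNNGCGC within 1 kb of a TSS were bound in 72.5% of 2859 genes and those without it in 50.3% of 5547. CpG-poor promoters were bound in 56.0% of 1354 genes with the word and 13.1% of 12178 without it. Peaks with 3 or more copies of the word near the summit had a lower median signal (80.3, 117 peaks) than those with 1 copy (365, 1849 peaks) or 2 (399.7, 253 peaks). Peaks without a copy had the lowest median (32.1, 8900 peaks). Overlapping copies within GC repeats were not told apart from separate sites here. The medians do not show that more separate sites go with weaker binding.

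Some of the strongest NRF1 peaks lay away from promoters of protein-coding genes. A peak in the HoxC cluster, 1049 bp past a TSS of Hoxc6, ranked 29 with a signal of 595 (chromosome 15, 102999124 to 102999479), although the Hox genes counted as bound had weak peaks. A peak 47798 bp from Srl ranked 18 (602; chromosome 16, 4475052 to 4475456) and held GCGCNNGCGC. A peak near Kcnrg ranked 20 (601; chromosome 14, 61648751 to 61649135), with its summit at offset -8 bp from the start of a long non-coding RNA gene, Gm27017. In the highest quintile 273 peaks lay over 1 kb from a TSS of a protein-coding gene, 19.8% of them at the TSS of another kind of gene, and 37.0% held the word at the summit.

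Replicate 1's own thresholded list lacked many of its strongest regions. Of the 100 regions with the highest signal in its unfiltered list 44 were missing from its thresholded list, of the next 400 there were 31 and of the 500 after those 5, yet each of these 1000 regions overlapped a peak of the optimal list. Among the top 100, the word stood at 70.5% of the missing regions and at 75% of those kept. Of the top 100 regions of replicate 2, and of the pooled list, 0 were missing. Rab3gap2, Ift172, Trappc1, Lig4 and Trim23 are genes with such peaks.

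The lists from both libraries differed mostly in weak peaks. Of the optimal peaks, 34.3% in the lowest quintile and 73.2% in the next overlapped a peak of the conservative list, against 100% in the highest, and 40.3%, 83% and 99.96% overlapped a peak of the pooled list of the second processing round. The optimal list was thus not contained in the larger list of the other round, which overlapped 84.3% of it.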
